A study of Mus musculus with 48 samples.

How the data were processed

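RNA-seq and Ribo-seq libraries were made from brain, retina, heart, kidney, liver and lung of wild-type C57BL/6 mice at E15.5 and P42, with 2 biological replicates per tissue, stage and assay per the labels, 48 libraries in all. Per the labels' protocols, frozen tissue was lysed with cycloheximide, footprints were prepared with an ARTseq kit after Ribo-Zero depletion, and messenger libraries were prepared with a poly(A) kit. Per the submitters' processing notes, base calls came from CASAVA 1.8.2, adapters were trimmed with cutadapt 1.8.1, reads were aligned with TopHat2 2.0.14 to GRCm38.p6 and exon reads were counted with featureCounts 1.6.2. The deposited values are TPM of exon reads in 4 tables of 12 libraries each, a table for each stage and assay. The annotation release and the features over which each TPM total was taken are not given in the sources used here. Read counts were not analysed here, so the depth per library, and the precision it gives, are unknown.

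The tables list 22055 genes by versioned Ensembl identifier. Of these, 22029 matched the GENCODE M21 annotation of GRCm38 without the version and 20636 with it, and 21972 are protein coding. Exons of 3726 genes overlap another gene and those of 140 a small structured RNA. Coordinates are those of that annotation, 1-based. Values were analysed as log2(TPM + 1). A gene was tested between tissues when at least 2 of the 24 libraries of the assay reached 1 TPM. Between stages, its mean over the libraries of the tissue in that assay also had to reach 1 TPM. For translational efficiency, at least 2 of the 48 libraries had to reach 1 TPM and mean RNA-seq 5 TPM. That floor applied at each stage of the tissue, or in each of the 6 tissues for comparisons between tissues. Genes below it at either stage have no efficiency test between stages. Linear models with a group for each tissue and stage were fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes variances that follow a trend with expression and Benjamini-Hochberg adjustment. The fit of an assay had 12 residual degrees of freedom and the fit over both assays 24, so variances are pooled over tissues. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.

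The comparisons were P42 against E15.5 in each tissue by mRNA, footprint and translational efficiency, changes shared by all tissues, genes higher in a tissue than in each other tissue at a stage, differences of translational efficiency between tissues, and similarity of tissues that share a germ layer. A gene was called at an adjusted p below 0.05 and a log2 difference of at least 1. The germ layer comparison used an exact permutation over the 15 ways to pair the tissues. Gene lists were written before the data were examined and tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over 588 tests of lists with at least 5 tested members. Of these, 273 passed at the preset correlation and 1 with an estimated correlation. A list of long noncoding RNA genes could not be tested, because 1 of its 41 members is in the tables. Which lists fit which tissue was decided after the data were seen.

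The genes named were chosen by a rule written before the data were examined. For each tissue it takes the 4 largest rises and 4 largest falls by mRNA among genes called in the same direction by both assays, and up to 4 called members of each list that passes and fits the tissue. It takes the 5 largest rises and falls of translational efficiency, the 4 most enriched genes of each tissue and stage, and the 10 largest changes in each direction over all tissues. A fixed set of 22 genes, from Igf2 to Atf4, was to be given in any case, and H19 too, which is not used here. A few genes that the rule names are not reported here. A gene listed at 0 in all libraries of a group has no fold change given.

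Alternatives set before the data were examined were pseudocounts of 0.25 and 4, median-of-ratios scaling, mitochondrially encoded genes left out, a replicate block, each library left out, no variance trend, libraries of the tissue alone, no filter and a stricter filter of 5 TPM with an RNA-seq floor of 20, a Ribo-seq floor of 1 TPM, library weights, Spearman correlation and an estimated correlation between genes. After seeing the data, 5 were added: listed genes rescaled to an equal sum, contrasts centred on the median gene, footprint calls below 5% of the highest tissue left out, and liver left out of 2 comparisons. The scripts were tested on simulated data with known changes. By mRNA 93.4% to 99.2% of genes changed by 1.5 log2 were called in the right direction, and 97.9% to 100% of those changed by 2, with 13202 to 14314 genes tested. By footprint the shares were 85.5% to 93.6% and 95.5% to 98%, with 11053 to 12974 genes tested. For translational efficiency they were 74.6% to 79.1% and 94.3% to 95.4%, with 9665 to 11725 genes tested. Unchanged genes were called in at most 0.044%, 0.078% and 0.162% of cases. The simulated stages had no shift of the median gene, and each gene varied alike in all groups of an assay. Only genes with log2(TPM + 1) above 4 in both assays at E15.5 were changed. These rates therefore do not cover errors from scaling, and the shares recovered do not cover genes at low values.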

Results

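Messenger RNA and ribosome occupancy were measured in brain, retina, heart, kidney, liver and lung of wild-type C57BL/6 mice on embryonic day 15.5 (E15.5) and postnatal day 42 (P42). RNA-seq of polyadenylated RNA counts messenger molecules, and Ribo-seq sequences the short fragments (footprints) that ribosomes shield from nuclease, so that its values follow the number of ribosomes on each message. The 6 tissues, 2 stages and 2 assays gave 24 groups of 2 biological replicates each, 48 libraries in all. Brain and retina derive from ectoderm, heart and kidney from mesoderm, and liver and lung from endoderm. The series title names a translatome of tissue development over space and time, and 3 questions follow from the design: what changed in each tissue between the stages, what set the tissues apart at each stage, and whether ribosome loading changed apart from message level. The deposited values were transcript abundances (TPM) for 22055 genes, and TPM keeps no read total, so the sequencing depth of the libraries is unknown.

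The listed genes summed to 48.94% to 93.38% of the TPM total in the RNA-seq libraries and to 23.14% to 61.13% in the Ribo-seq libraries. Between 10525 and 14572 genes reached 1 TPM by RNA-seq, and between 8944 and 13236 by Ribo-seq. The 13 mitochondrially encoded genes took 0.34% to 55.51% of the TPM total in RNA-seq libraries and 0.13% to 7.19% in Ribo-seq libraries. Replicates correlated across genes with Pearson's r of 0.967 to 0.998 by RNA-seq and 0.948 to 0.998 by Ribo-seq. Replicate 2 of the E15.5 kidney RNA-seq group stood apart from replicate 1, with the lowest sum of all RNA-seq libraries, 48.94%. Values below are means ± SD over 2 replicates. Changes are P42 minus E15.5 on the log2(TPM + 1) scale with standard errors (SE), and adjusted p-values come from limma. The variance of a gene is pooled over tissues, so where it is near 0 in most tissues, its SE and p-value can be too small. Called genes passed an adjusted p of 0.05 and a log2 difference of 1 in size.

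The median gene shifted between the stages in most tissues. By mRNA the median change was -0.60 in brain, -0.23 in retina, -1.61 in heart, -0.81 in kidney, -0.89 in liver and -1.11 in lung. By footprint it was -0.01, 0.08, -1.01, -0.74, -0.85 and -0.21 in the same order. Medians of gene lists, where given as above or against all genes, have the median of all tested genes taken off. Counts of genes called between the stages are also given as kept under every scaling tried. Named genes were called under every scaling in the layer given unless stated otherwise, and mitochondrially encoded genes have no value where they are left out. Gene lists were tested with camera, and only the mRNA rise of the photoreceptor list in retina also passed with an estimated correlation between genes. Counts of list members called were the same when adjusted over the list alone, except where both are given. Stage and deposited table coincide, so a difference between tables cannot be separated from a difference between stages.

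In brain, genes of myelin, synapses and glia rose and genes of neural progenitors fell. Mobp (chromosome 9, 120149707 to 120181484, GRCm38), which encodes a myelin protein, went from 0.105 ± 0.0111 to 521 ± 89.0 TPM by RNA-seq, a change of 8.87 (SE 0.112, adjusted p = 4.72e-24). All 19 tested myelin genes rose by mRNA (median 4.82 above all genes, adjusted p = 7.47e-24, adjusted p = 0.168 with an estimated correlation). Among them Mal rose by 7.20, Mag by 6.61 and Mbp, myelin basic protein, from 13.8 ± 0.876 to 1389 ± 279 TPM. Of 32 genes of mature neurons and synapses, 22 rose and 1 fell (median 2.49 above all genes, adjusted p = 1.25e-15, adjusted p = 0.262 with an estimated correlation). Nrgn, a calmodulin-binding protein of dendrites, rose by 7.49 to 6081 ± 899 TPM, Pvalb by 5.72, the glutamate transporter gene Slc17a7 by 5.58 and Camk2a by 5.33.

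Astrocyte genes rose for 11 of 14 in brain (median 3.28 above all genes, adjusted p = 5.55e-12, adjusted p = 0.262 with an estimated correlation). The intermediate filament gene Gfap rose by 6.23, S100b by 6.22, the water channel gene Aqp4 by 3.71 and the glutamate transporter gene Slc1a2 by 3.55. All 14 microglia genes rose (adjusted p = 1e-10, adjusted p = 0.292 with an estimated correlation), among them Ctss by 3.08, C1qa by 2.62, Tmem119 by 2.57 and C1qb by 2.41. Gpr37l1 and Fam107a also ranked among the largest rises, at 7.38 and 7.35. Of 24 genes of neural progenitors and immature neurons, 23 fell (median -2.41 against all genes, adjusted p = 1.63e-10, adjusted p = 0.292 with an estimated correlation). Igfbpl1 fell by 6.97 from 444 ± 60.6 TPM, the microtubule gene Dcx of migrating neurons by 6.52, Sox11 by 6.29, and Eomes, a marker of intermediate progenitors, fell by 5.91. Gpc2, whose exons overlap Gm43720, fell by 6.73, Cd24a fell by 6.71 and the axon guidance gene Draxin fell by 6.59.

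Footprints in brain moved in the same directions. Of the synaptic genes, 31 of 32 rose by footprint (adjusted p = 3.34e-13, adjusted p = 0.426 with an estimated correlation), and of the myelin genes 18 of 19 rose (adjusted p = 5.41e-13, adjusted p = 0.292 with an estimated correlation). Footprints of progenitor genes fell for 22 of 24 (adjusted p = 7.73e-12, adjusted p = 0.338 with an estimated correlation). Astrocyte footprints rose for 12 of 14 (adjusted p = 2.81e-07, adjusted p = 0.292 with an estimated correlation) and microglia footprints for 13 of 14 (adjusted p = 0.000112, adjusted p = 0.547 with an estimated correlation). In all, 1694 genes rose and 5203 fell of 14449 tested by mRNA, and 2685 rose and 2353 fell of 13312 by footprint. Median-of-ratios scaling gave 3243 higher and 2216 lower by mRNA, centring on the median 3060 and 2550, and 1632 and 2197 genes were called under every scaling, or 2450 and 1893 by footprint. Rescaling the listed genes to an equal sum gave 2528 higher and 3202 lower by footprint in brain, so which direction held the majority depended on the scaling in both assays. By both assays 1269 genes were higher, 1919 lower and 64 opposite, of 12954 tested in both.

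In retina, photoreceptor genes rose, some of them from near 0. Gnat1 (chromosome 9, 107674474 to 107679712), the rod transducin gene, rose from 0.760 ± 0.0289 to 20480 ± 2567 TPM, a change of 13.50 (SE 0.162, adjusted p = 1.86e-25). All 35 photoreceptor genes rose by mRNA (median 8.95 above all genes, adjusted p = 1.97e-38, adjusted p = 0.0454 with an estimated correlation) and all 35 by footprint (adjusted p = 6.95e-32, adjusted p = 0.106 with an estimated correlation). Rcvrn rose by 12.03 and Prph2, a structural protein of outer segment discs, by 11.70. Footprints of Gnat1 were 8.60 ± 6.51 TPM at E15.5 and 5991 ± 377 TPM at P42. Genes of mature neurons rose for 26 of 32 with 2 lower (adjusted p = 7.55e-11, adjusted p = 0.326 with an estimated correlation), led by Slc17a7 at 9.35, Pvalb at 5.83, the GABA synthesis gene Gad1 at 5.69 and Calb1 at 5.18.

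Retinal progenitor and ganglion cell genes fell for 22 of 25 (median -2.54 against all genes, adjusted p = 7.05e-12, adjusted p = 0.243 with an estimated correlation). Fgf15 fell by 10.66 from 1706 ± 136 TPM, Atoh7, needed for ganglion cell formation, by 9.21, the secreted Wnt modulator gene Sfrp2 fell by 8.30 and Foxn4 fell by 7.70. Footprints of this list fell for 20 of 25 (adjusted p = 3.53e-11, adjusted p = 0.288 with an estimated correlation). The topoisomerase gene Top2a of dividing cells fell by 8.22, and 49 of 50 cell cycle genes fell by mRNA (adjusted p = 2.31e-23, adjusted p = 0.375 with an estimated correlation). Of 79 ribosomal protein genes 77 fell by mRNA (median -1.50 against all genes, adjusted p = 3.15e-12, adjusted p = 0.639 with an estimated correlation), 67 of them under every scaling.

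Markers of neighbouring eye tissues moved with the retinal lists. Lens crystallin genes rose for 13 of 18 (adjusted p = 5.16e-06, adjusted p = 0.547 with an estimated correlation). Their P42 replicates lay far apart, with Crygs at 33.4 ± 23.8, Crygb at 37.4 ± 19.5, Cryab at 108 ± 35.8 and Crybb2 at 52.5 ± 40.6 TPM, the last listed at 0 in E15.5 RNA-seq. Genes of the retinal pigment epithelium rose for 6 of 11 with 1 lower (adjusted p = 0.00845, adjusted p = 0.338 with an estimated correlation). Rlbp1 rose by 5.36, the visual cycle gene Rpe65 by 4.41, Rgr by 4.18 and Lrat by 2.01. By mRNA 2601 genes rose and 3455 fell of 14015, against 3063 and 2362 under median-of-ratios scaling and 3135 and 2685 after centring on the median. By footprint 2545 rose and 1940 fell of 11974. Under every scaling 2538 rose and 2362 fell by mRNA, and 2346 and 1904 by footprint, and by both assays 1701 were higher, 1692 lower and 23 opposite, of 11849.

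In heart, fetal cardiac genes fell and mitochondrially encoded genes rose. Tnni1 (chromosome 1, 135779434 to 135810989), the slow skeletal troponin I of the fetal heart, fell by 10.30 (SE 0.711, adjusted p = 1.79e-11) from 1425 ± 83.6 to 0.130 ± 0.0101 TPM. The cardiac form Tnni3 went from 1210 ± 73.4 to 3246 ± 162 TPM (1.42, adjusted p = 7.09e-05), while its footprint change was 0.23 and not called. The myosin gene Myh7 fell by 6.63 from 1813 ± 43.3 TPM, and Myh6, the adult myosin heavy chain in mice, rose by 1.31 (SE 0.377, adjusted p = 0.00264) to 1378 ± 222 TPM. The atrial light chain gene Myl7 and Myl4 each fell by 7.04, and Plagl1 by 6.98. Fetal cardiac genes fell for 13 of 15 (median -1.65 against all genes, adjusted p = 0.0457, adjusted p = 0.748 with an estimated correlation), 7 under every scaling, and all 15 by footprint (adjusted p = 0.000359, adjusted p = 0.492 with an estimated correlation).

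Of 24 adult sarcomere and calcium handling genes in heart, 7 rose and 1 fell by mRNA (median 1.53 above all genes, adjusted p = 3.34e-14, adjusted p = 0.335 with an estimated correlation). Their median change itself was -0.08. Ckmt2, a mitochondrial creatine kinase, rose by 5.23, Tcap by 4.36, myoglobin (Mb) by 3.03 and Myoz2 by 2.11. By footprint 6 rose and 4 fell (adjusted p = 0.000146, adjusted p = 0.631 with an estimated correlation), and Myoz2 was not called there at 0.67. The largest rises by both assays were Rpl3l at 6.55 by mRNA and 5.14 by footprint, a ribosomal protein gene of striated muscle, followed by Tuba8 at 5.67, the lipid droplet gene Plin5 at 5.56 and Ucp3 at 5.44. All 13 mitochondrially encoded genes rose (median 3.53 above all genes, adjusted p = 2.42e-27, adjusted p = 0.145 with an estimated correlation).

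Fatty acid oxidation genes of heart rose for 9 of 28 and fell for 3 (median 1.94 above all genes, adjusted p = 1.29e-19, adjusted p = 0.292 with an estimated correlation), of which 5 rose and 0 fell under every scaling. Pdk4, which restrains pyruvate oxidation, rose by 2.25. The regulator genes Ppargc1a and Ppara fell by 2.39 and 2.02, calls that other scalings did not keep, and the Ppara footprint change was 0.51 and not called. Nuclear genes of oxidative phosphorylation lay 1.90 above all genes in the median (adjusted p = 1.08e-34, adjusted p = 0.374 with an estimated correlation), with 5 of 75 called higher and 3 lower, and 1 higher under every scaling. In all, 349 genes rose and 9529 fell of 12780 by mRNA, and 1275 rose and 6334 fell of 12521 by footprint. Median-of-ratios scaling gave 2576 and 1839 by mRNA and 2442 and 1372 by footprint, and centring on the median 2039 and 1515, and 2285 and 1444. Rescaling the listed genes to an equal sum gave 1825 and 3530 by footprint, so the lower majority in heart depended on the scaling. Under every scaling 290 rose and 1250 fell by mRNA, and 1275 and 1187 by footprint. Footprint counts in heart also include genes whose footprints were far higher in another tissue. With calls below 5% of the highest tissue left out, 1081 rose and 6295 fell by footprint with the deposited scaling. By both assays 231 genes were higher, 5735 lower and 61 opposite of 11484, of which 211 higher and 606 lower held under every scaling.

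In kidney, tubule genes rose and nephron progenitor genes fell. Kap (chromosome 6, 133849851 to 133853762), an androgen-responsive gene of the proximal tubule, rose from 1.07 ± 0.587 to 51130 ± 14080 TPM, a change of 14.60 (SE 0.184, adjusted p = 2.1e-24). Umod, the abundant urinary protein of the thick ascending limb, rose by 9.34 (SE 0.135) to 2806 ± 283 TPM, Klk1 by 10.42, the inositol oxygenase gene Miox by 9.52, Akr1c21 by 9.42 and the dicarboxylate transporter gene Slc13a3 by 6.62. Of 31 tubule transport genes 30 rose by mRNA (median 5.12 above all genes, adjusted p = 4.56e-31, adjusted p = 0.243 with an estimated correlation) and 30 by footprint (adjusted p = 6.49e-20, adjusted p = 0.338 with an estimated correlation). Fatty acid oxidation genes rose for 24 of 27 (adjusted p = 1.09e-14, adjusted p = 0.355 with an estimated correlation), 18 under every scaling. Oxidative phosphorylation genes rose for 72 of 75 (adjusted p = 8.31e-24, adjusted p = 0.492 with an estimated correlation), 39 under every scaling.

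Nephrogenesis genes fell for 21 of 24 by mRNA (median -2.44 against all genes, adjusted p = 1.8e-06, adjusted p = 0.547 with an estimated correlation) and 23 of 24 by footprint (adjusted p = 2.64e-07, adjusted p = 0.243 with an estimated correlation). Six2 (chromosome 17, 85684277 to 85688274), which maintains the nephron progenitor pool, fell by 5.32 (SE 0.219) from 140 ± 41.7 TPM, Cited1 by 5.69, the ureteric bud ligand gene Gdnf by 5.18 and its receptor gene Gfra1 fell by 4.70. The growth factor gene Igf2 fell by 9.27 from 1071 ± 344 TPM, and Gm49394, whose exons overlap it, by 9.36. Mest, whose exons overlap Copg2, fell by 7.91.

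Genes of other organs were present in the E15.5 kidney RNA-seq libraries. Adrenal steroid synthesis genes fell for 12 of 13 (median -4.16 against all genes, adjusted p = 4.9e-06, adjusted p = 0.487 with an estimated correlation) and 12 of 14 by footprint (adjusted p = 7.23e-06, adjusted p = 0.292 with an estimated correlation). Hsd3b1 fell by 7.81 from 246 ± 91.9 TPM, Cyp11b1 fell by 7.11 and Cyp11a1 by 6.08, and Cyp21a1 was at 192 ± 66.7 TPM at E15.5 and listed at 0 at P42. Alb, serum albumin, was at 1520 ± 522 TPM at E15.5 and 7.52 ± 0.931 at P42, and Afp, its fetal counterpart, at 775 ± 335 and 0.9899 ± 0.462. By mRNA 1852 genes rose and 6200 fell of 14129, and by footprint 1574 and 5203 of 12940. Median-of-ratios scaling gave 3542 and 3008 by mRNA and 3030 and 2151 by footprint, and centring on the median 3419 and 2887, and 2848 and 2363. The counts kept under every scaling were 1368 and 2738 by mRNA and 1550 and 2054 by footprint. By both assays 1290 genes were higher, 4320 lower and 10 opposite, of 12722.

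In liver, blood formation genes and fetal proteins fell while hepatocyte metabolism rose. Afp (chromosome 5, 90490737 to 90508907) fell by 12.34 (SE 0.325, adjusted p = 2.53e-19) from 13330 ± 811 to 1.595 ± 0.461 TPM and by 13.70 by footprint. Hepatocyte genes rose for 38 of 39, or 39 adjusted over the list alone (median 5.76 above all genes, adjusted p = 1.42e-35, adjusted p = 0.168 with an estimated correlation), and 35 of 39 by footprint (adjusted p = 4.24e-33, adjusted p = 0.243 with an estimated correlation). The cytochrome gene Cyp2e1 rose by 12.05 (SE 0.340) from 0.858 ± 0.0259 to 7894 ± 846 TPM, Apoc3 by 10.45 and Cyp1a2 by 9.21. Serpina3k and the major urinary protein gene Mup3 were listed at 0 in E15.5 RNA-seq and reached 8374 ± 711 and 7584 ± 1423 TPM. Alb was already at 32300 ± 3771 TPM at E15.5 and at 92350 ± 6254 at P42. Its mRNA change of 1.52 (SE 0.682, adjusted p = 0.0449) was not kept under every scaling, and its footprint change of 0.32 was not called.

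All 28 erythroid genes fell in liver by mRNA (median -6.79 against all genes, adjusted p = 3.84e-13, adjusted p = 0.355 with an estimated correlation) and by footprint (adjusted p = 5.75e-13, adjusted p = 0.320 with an estimated correlation). The red cell anion exchanger gene Slc4a1 fell by 11.12 from 2632 ± 205 TPM, the blood group gene Kel by 9.32, and Hemgn fell by 9.11. The beta globin genes Hbb-bt and Hbb-bs fell by 8.63 and 8.01, the latter from 83470 ± 9327 TPM. Fetal liver genes fell for 12 of 17 with 1 higher (adjusted p = 0.0183, adjusted p = 0.732 with an estimated correlation). They included Igf2 at -9.94, the glypican gene Gpc3 at -7.75 and Dlk1, which was at 221 ± 24.04 TPM at E15.5 and listed at 0 at P42. By footprint 10 of 15 fell and 2 rose (adjusted p = 0.0134, adjusted p = 0.547 with an estimated correlation).

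Replication-dependent histone genes fell for 46 of 47 by mRNA in liver (median -7.39 against all genes, adjusted p = 6.95e-16, adjusted p = 0.426 with an estimated correlation). Hist1h1a fell by 11.68, and Hist2h2bb was at 4969 ± 8.46 TPM at E15.5 and listed at 0 at P42. These falls rest on the 2 E15.5 liver RNA-seq libraries, where histone messages summed to 29758 and 39214 TPM against 69.3 to 477 TPM in the other E15.5 RNA-seq libraries. Ccnb1ip1, whose exons overlap the small RNA gene Rpph1, fell by 12.13 from 5871 ± 1009 TPM. By mRNA 1743 genes rose and 6091 fell of 12967, and by footprint 1155 and 4959 of 11274. Median-of-ratios scaling gave 3900 and 3196 by mRNA and 2795 and 2156 by footprint, and centring on the median 3390 and 2940, and 2323 and 2181. The counts kept under every scaling were 1387 and 2711 by mRNA and 1153 and 1925 by footprint. By both assays 955 genes were higher, 3872 lower and 44 opposite, of 11046.

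In lung, secretory, alveolar and immune genes rose and branching genes fell. Scgb1a1 (chromosome 19, 9083636 to 9087958), the secretoglobin of club cells, rose by 16.24 (SE 0.389, adjusted p = 2.55e-19) from 2.61 ± 1.10 to 279600 ± 83720 TPM. Of 22 alveolar epithelium genes 18 rose and 1 fell (median 4.38 above all genes, adjusted p = 5.2e-22, adjusted p = 0.218 with an estimated correlation), and 21 rose by footprint (adjusted p = 3.34e-13, adjusted p = 0.292 with an estimated correlation). The surfactant gene Sftpc was at 3639 ± 564 TPM at E15.5 and rose by 3.23 (SE 0.316) to 33880 ± 1986, Chil1 rose by 8.52, the collectin genes Sftpd and Sftpa1 by 8.43 and 6.03 and the water channel gene Aqp5 by 6.38. Airway genes rose for 13 of 17 (adjusted p = 3.1e-17, adjusted p = 0.0964 with an estimated correlation) and 14 by footprint (adjusted p = 8.21e-10, adjusted p = 0.292 with an estimated correlation). Scgb3a1 rose by 10.42, Bpifa1 by 6.34 and the club cell cytochrome gene Cyp2f2 by 5.61, and outside these lists Inmt rose by 11.38 and Chil3 by 9.26.

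Genes of leukocytes and antigen presentation rose in lung for 24 of 25 (median 3.76 above all genes, adjusted p = 8.92e-25, adjusted p = 0.168 with an estimated correlation), and all 25 by footprint (adjusted p = 2.07e-13, adjusted p = 0.335 with an estimated correlation). The class II genes H2-Ab1, H2-Eb1 and H2-Aa rose by 6.18, 5.93 and 5.90, and the invariant chain gene Cd74 by 5.89. Endothelial genes rose for 9 of 15 (adjusted p = 1.16e-07, adjusted p = 0.446 with an estimated correlation) and 13 by footprint (adjusted p = 3.31e-06, adjusted p = 0.446 with an estimated correlation). Ramp2 rose by 2.42, Vwf by 2.34, the tight junction gene Cldn5 by 1.91 and Egfl7 by 1.70. Progenitor and branching genes fell for 18 of 22 (adjusted p = 0.00184, adjusted p = 0.707 with an estimated correlation), 11 under every scaling, and 11 by footprint (adjusted p = 0.0021, adjusted p = 0.731 with an estimated correlation). Sox9 fell by 5.09, Wnt7b by 4.55, Etv4 by 4.12 and the Hedgehog effector gene Gli1, which overlaps Arhgap9, by 4.06. All 10 cartilage genes fell in lung too (adjusted p = 0.000137, adjusted p = 0.492 with an estimated correlation), and Sox9 is on both lists.

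The largest falls in lung were Dlk1 by 8.81, the fibrillin gene Fbn2, which fell by 8.04, Cldn6 by 7.79 and Igf2 by 7.55. Cardiac messages were present in the E15.5 lung RNA-seq libraries, with Myh6 at 44.2 ± 26.9 and the atrial hormone gene Nppa at 108 ± 133 TPM. The globin gene Hbb-bs rose by 1.01 in lung (adjusted p = 0.0104), a call other scalings did not keep, and Hbb-bt changed by -0.27 and was not called. By mRNA 1443 genes rose and 7647 fell of 14292, and by footprint 2470 and 3024 of 13261. Median-of-ratios scaling gave 3421 and 2282 by mRNA and 3051 and 1902 by footprint, centring on the median 3309 and 2423, and 2894 and 2342, and rescaling to an equal sum 1865 and 5273 by footprint. The counts kept under every scaling were 1363 and 2085 by mRNA and 1860 and 1902 by footprint. By both assays 1187 genes were higher, 2731 lower and 63 opposite, of 12960.

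**Figure D1:**
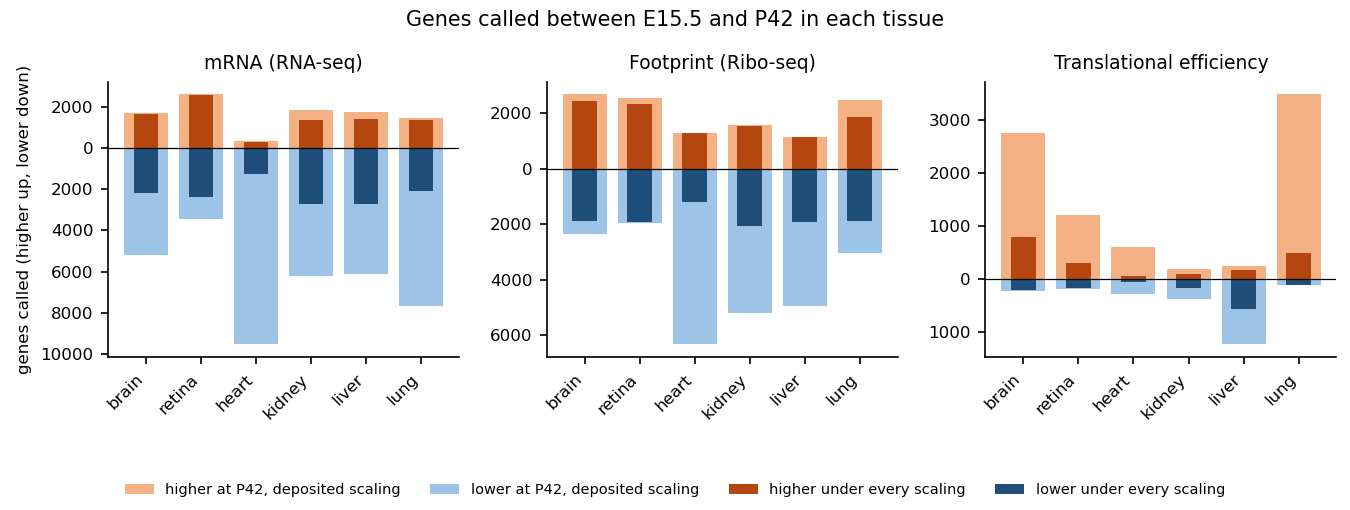
Number of genes called higher (upward bars) and lower (downward bars) at P42 than at E15.5 in each of 6 tissues, by mRNA, footprint and translational efficiency; pale bars are calls with the deposited scaling and dark inner bars those kept under every scaling tried. By mRNA 9529 genes were lower in heart with the deposited scaling and 1250 under every scaling, while 349 and 290 were higher.

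**Figure D2:**
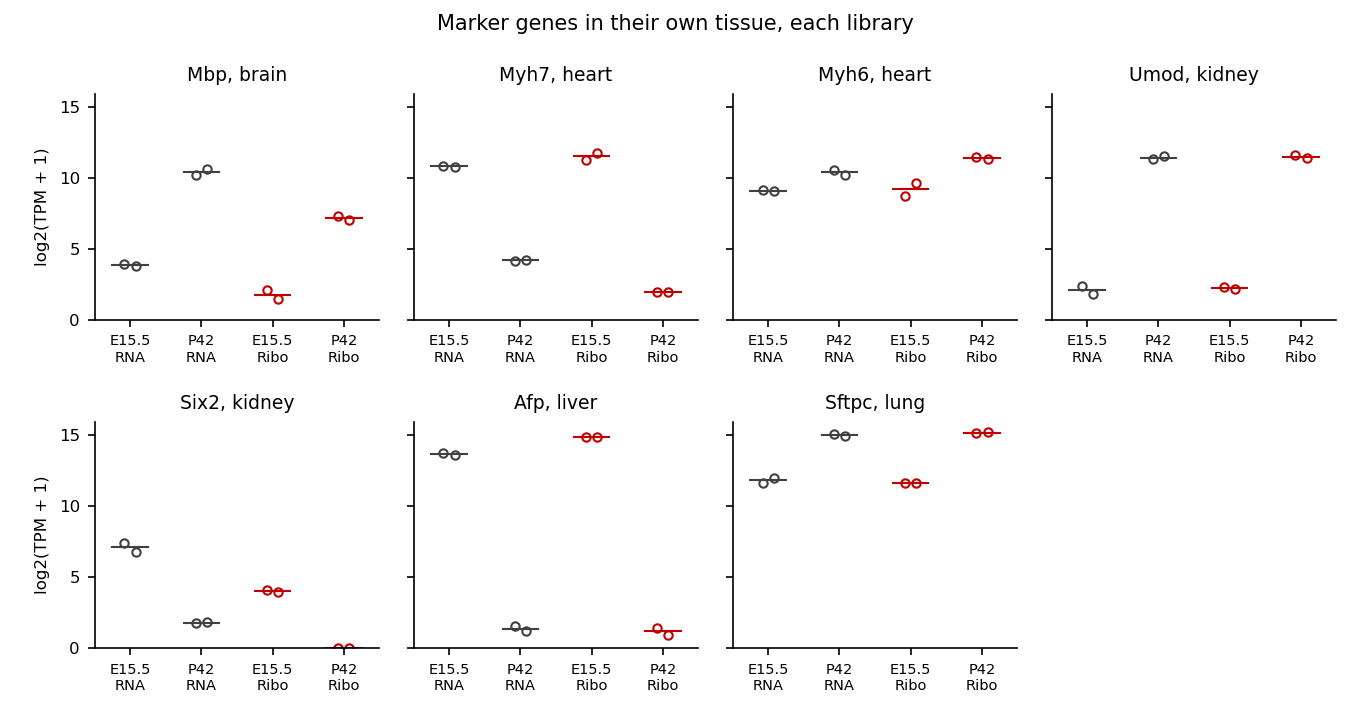
Expression of 7 marker genes in their own tissue as log2(TPM + 1), with an open circle for each of 2 replicate libraries and a line at their mean, at E15.5 and P42 by RNA-seq (grey) and Ribo-seq (red). Umod in kidney went from 3.38 to 2806 TPM by RNA-seq, and Myh7 in heart from 1813 to 17.3 TPM.

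Changes of message and footprint went together across genes in each tissue. Pearson's r between the log2 changes of the 2 assays was 0.816 in brain, 0.905 in retina, 0.727 in heart, 0.915 in kidney, 0.877 in liver and 0.862 in lung. The SD of footprint changes was 0.955, 0.856, 0.925, 0.931, 0.878 and 0.940 times that of mRNA changes. Genes are not independent replicates, so no test was made of these values.

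Genes that fell in all 6 tissues included most members of the cell cycle list. By mRNA 26 genes rose and 1147 fell in every tissue of 10824 tested in all, and by footprint 34 rose and 650 fell of 9161. Independent lists of these sizes would share 0.0006678 rising and 104 falling genes by mRNA, and 0.002086 and 8.377 by footprint. Median-of-ratios scaling gave 197 and 328 by mRNA and 128 and 345 by footprint, and centring on the median 169 and 328, and 97 and 380. By both assays 11 genes rose and 429 fell in every tissue. Of these, 142 falling genes held under every scaling, as did the rising genes, except that mt-Nd2, mt-Nd3 and mt-Nd4 among them have no value where mitochondrially encoded genes are left out. The embryonic globin gene Hbb-y (chromosome 7, 103851749 to 103853216) fell most on average, by 6.13 (SE 0.083, adjusted p = 1.8e-23). The proliferation marker gene Mki67 fell by 5.95, Top2a by 5.94, the DNA methylation maintenance gene Uhrf1 by 5.58, the spindle motor gene Kif11 by 5.37, Fbn2 by 5.28, Ube2c, which overlaps Tnnc2, by 5.26, cyclin B1 (Ccnb1) by 5.26, Pclaf by 5.26 and the ribonucleotide reductase gene Rrm2 by 5.25.

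Of the 50 cell cycle genes, 41 were among the 429 that fell everywhere by both assays, and 4 of 18 imprinted growth genes were. In single tissues the cell cycle list fell for 46 of 50 genes in brain, 49 in retina, 50 in heart, 50 in kidney, 48 in liver and 50 in lung by mRNA. The corresponding adjusted p-values were 5.12e-12, 2.31e-23, 8.57e-15, 7.11e-15, 1.51e-14 and 6.69e-14, and adjusted p = 0.375 to 0.547 with an estimated correlation. Mki67 fell least in brain, by 4.60, and in liver, where the fall was largest, it fell by 7.89. Igf2 (chromosome 7, 142650766 to 142666816) fell by 2.04 in brain and 6.81 in heart, and its change in retina, -0.68, was not called. Lin28b, which blocks maturation of let-7 microRNAs, fell by 2.35 in brain and 2.28 in retina, was listed at 0 in P42 liver and was not tested in heart, kidney and lung.

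Of the 11 genes that rose in every tissue by both assays, 3 were mitochondrially encoded. The circadian transcription factor gene Dbp rose by 4.58 on average (SE 0.089, adjusted p = 1.04e-21) by mRNA and 3.94 by footprint, with exons that overlap Sphk2. Ly6a rose by 4.24, the interferon-induced gene Ifit3 by 3.54, Fgf1 by 3.20, Klf9 by 3.03, Ephx1 by 2.96 and Coq8a, which overlaps Cdc42bpa, by 2.10. The mitochondrially encoded genes mt-Nd3, mt-Nd2 and mt-Nd4 of respiratory complex I rose by 3.01, 2.80 and 2.41, and mt-Nd4 overlaps mt-Nd4l. Time of day at collection is not given in the sources used here.

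Tissues were set apart at each stage by genes called higher in a tissue than in each of the other 5. At E15.5 brain had 1260 such genes by mRNA and 1214 by footprint (818 by both), retina 343 and 155 (131), heart 498 and 561 (413), kidney 307 and 337 (254), liver 1075 and 1040 (792) and lung 471 and 279 (242). Neurod6, a transcription factor gene of cortical neurons, led in brain with 498 ± 71.5 TPM and at least 8.42 log2 above every other tissue, with Neurod2 at 253 and Tbr1 at 106 TPM. Leading genes in retina included Atoh7 at 1088 ± 22.7 TPM, Rax at 387 and Dapl1 at 881, and heart was led by the contractile genes Myl2 at 8445 ± 204 and Myl3 at 2654, Mb at 1157 and Pln, the regulator of the sarcoplasmic calcium pump, at 2124 TPM. Lung was led by Sftpc, Cldn18 at 204 ± 25.2, Tbx4 at 176 and Sftpb at 194 TPM. In kidney the leading genes were the adrenal genes Cyp21a1 and Cyp11b1, then Hoxc10 at 110 ± 34.9 and Hoxa10 at 100 ± 37.8 TPM. In liver the 4 leading genes were replication-dependent histones, with Hist1h1b at 2841 ± 556, Hist2h4 at 1036 ± 237, Hist1h3g at 667 and Hist1h3f at 420 TPM. The smallest difference of Hist2h4 from another tissue was 8.78 by mRNA and 1.73 by footprint, and this ranking too rests on the E15.5 liver RNA-seq libraries that stand apart in histone messages.

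At P42 brain had 1283 enriched genes by mRNA and 1819 by footprint (1047 by both), retina 2591 and 479 (464), heart 244 and 840 (192), kidney 718 and 589 (508), liver 588 and 546 (491) and lung 1193 and 1649 (959). Leading genes in brain included Mobp, Cldn11 and Ddn, at least 8.80, 7.88 and 7.79 above every other tissue. Those in retina included Pdc at 10.78, Rcvrn at 10.75 and Prph2 at 10.56, and heart was led by Myl2 at 11.38, Myl3 at 9.84, Pln at 8.68 and Mb at 8.47. Kidney was led by Kap at 14.004, Klk1 at 11.76, Umod at 11.44 and Miox at 10.98, and liver by Alb at 13.32, Apoa1 at 12, Serpina3k at 11.99 and Ahsg at 11.87. In lung Scgb1a1 stood at least 16.81 above every other tissue by mRNA and 7.25 by footprint, followed by Sftpc at 12.35, Sftpb at 11.61 and Scgb3a2 at 11.18 by mRNA. Genes enriched at both stages numbered 543 in brain, 167 in retina, 171 in heart, 171 in kidney, 274 in liver and 209 in lung by mRNA. All these counts of enriched genes are with the deposited scaling only. Mitochondrially encoded genes took 54.25% and 55.51% of the TPM total in P42 heart RNA-seq libraries, and 7.19% and 6.83% in P42 heart Ribo-seq libraries. In the P42 Ribo-seq libraries the listed genes summed to 26.2% and 27.52% of the TPM total in retina and 61.13% and 53.2% in lung. By RNA-seq they summed to 88.44% and 88.67% in retina and 83.13% and 93.38% in lung. The counts by mRNA and footprint in heart, retina and lung are therefore not directly comparable.

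Whether tissues that share a germ layer resemble each other more could not be decided with 6 tissues. The mean correlation of the 3 pairs that share a layer was 0.782 at E15.5 and 0.659 at P42 by mRNA, against 0.680 and 0.506 for the other pairs, and 0.811 and 0.655 against 0.719 and 0.503 by footprint. At E15.5 by mRNA the pairs that share a layer stood at 0.874 for brain and retina, 0.821 for heart and kidney and 0.651 for liver and lung, while kidney and lung stood at 0.891 and heart and lung at 0.865. In each of the 4 comparisons 3 of the 15 ways to pair the 6 tissues gave as large a difference, an exact one-sided permutation p of 0.2, and 0.2 adjusted over the 4. The smallest p this design allows is 0.067, so it could not reach 0.05.

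Translational efficiency, the footprint to mRNA ratio of a gene, fell for most ribosomal protein genes in liver, kidney and heart. Its median change was 0.55 in brain, 0.39 in retina, 0.20 in heart, -0.09 in kidney, -0.30 in liver and 0.82 in lung. The efficiency of ribosomal protein genes fell for all 79 in liver (median change -3.06, adjusted p = 4.83e-55, adjusted p = 0.236 with an estimated correlation), 78 of them under every scaling. It fell for 62 of 79 in kidney, or 70 adjusted over the list alone and 53 under every scaling (median -1.71, adjusted p = 3.59e-45, adjusted p = 0.262 with an estimated correlation). In heart it fell for 66, or 68 adjusted over the list alone and 30 under every scaling (median -1.67, adjusted p = 1.38e-48, adjusted p = 0.243 with an estimated correlation). Fewer members were called in the next tissues, where the list passed against other genes. It fell for 27 of 79 in lung, or 26 adjusted over the list alone (median -0.79, adjusted p = 9.89e-41, adjusted p = 0.287 with an estimated correlation), and for 21 of 79 in brain, or 20 (median -0.53, adjusted p = 6.33e-20, adjusted p = 0.477 with an estimated correlation). In retina 6 rose and 0 fell, the list did not pass (adjusted p = 0.143) and its median change was 0.19. In liver Rpl39 fell by 5.25, Rps20, which overlaps the small RNA gene Gm24016, by 4.89, Rpl36a by 4.89 and Rpl3 fell by 1.795, and in heart Rpl24 fell by 2.52. The liver changes of efficiency rest on the E15.5 liver RNA-seq libraries, which differ from the other E15.5 RNA-seq libraries in histone messages (29758 and 39214 TPM against 69.3 to 477), so library content cannot be separated from translation there.

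The elongation factor gene Eef1a1 fell in efficiency by 3.99 in liver (adjusted p = 2.16e-09) and 2.04 in kidney (adjusted p = 0.00063) and was not called in the other 4 tissues. Its mRNA went from 2898 ± 123 to 2493 ± 232 TPM in liver, a change of -0.22 that was not called, while its footprints went from 1110 ± 103 to 60.8 ± 21.6 TPM. Translation factor genes fell in efficiency for 20 of 36 in liver (adjusted p = 7.04e-07, adjusted p = 0.592 with an estimated correlation) and 11, or 12 adjusted over the list alone, in kidney (adjusted p = 5.61e-09, adjusted p = 0.539 with an estimated correlation). Nuclear oxidative phosphorylation genes fell for 46 of 75 in liver (adjusted p = 2.18e-11, adjusted p = 0.606 with an estimated correlation) and 22, or 31 adjusted over the list alone, in kidney (adjusted p = 5.82e-16, adjusted p = 0.539 with an estimated correlation). In heart 29 of them fell, or 32 adjusted over the list alone and 1 under every scaling (adjusted p = 8.96e-21, adjusted p = 0.480 with an estimated correlation). The iron storage gene Fth1 fell in efficiency by 2.74 in liver, 2.51 in kidney and 2.00 in brain, while its mRNA rose by 1.07, 2.93 and 2.11, the liver rise not under every scaling. Ftl1, the light chain, fell by 2.85 in liver. Its log2 ratio was lower at P42 in every tissue but retina, where it went from -5.554 to -4.16. Atf4, a stress-responsive factor with upstream reading frames, was not called in efficiency in any tissue.

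Mitochondrially encoded genes rose in efficiency for 6 of 11 in kidney, or 8 adjusted over the list alone (adjusted p = 9.22e-09, adjusted p = 0.338 with an estimated correlation), and fell for 7 of 10 in liver (adjusted p = 0.0221, adjusted p = 0.737 with an estimated correlation). In kidney mt-Atp8, which overlaps mt-Atp6, rose by 3.42 and mt-Nd5, which overlaps mt-Nd6, by 2.89. Myh7 fell in efficiency by 2.93 in heart (SE 0.777, adjusted p = 0.00798), beyond the fall of its message. In liver Gpam (chromosome 19, 55067268 to 55127238), which starts triglyceride synthesis, rose in efficiency by 4.10 (SE 0.425, adjusted p = 1.21e-08). Its RNA went from 96.3 ± 9.31 to 5.22 ± 0.388 TPM and its footprints from 56.6 ± 6.72 to 63.0 ± 17.3 TPM. The lipid sensor gene Ppara rose in efficiency by 3.67 in liver (SE 0.419), with footprints of 13.5 ± 1.18 and 105 ± 40.7 TPM. In brain Cdr1 rose by 4.10 (SE 0.583, adjusted p = 2.27e-06), the GABA receptor gene Gabrb2 by 3.71 (SE 0.298) and Pfkp, which overlaps Pitrm1, by 4.10, and in heart Ybx2 rose by 3.504.

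The histone genes Hist1h2bc and Hist1h1c, both on the replication-dependent list, fell in efficiency in brain (-5.56 and -4.79), retina (-7.28 and -6.84), heart (-3.67 and -3.38), kidney (-5.02 and -3.44) and lung (-4.80 and -3.08). Hist1h1c in E15.5 brain was at 11.0 ± 0.743 TPM by RNA-seq and 654 ± 358 TPM by footprint, and RNA-seq here counts polyadenylated messages, so these ratios are not a measure of translation alone. Many of the other largest changes belonged to genes whose exons overlap another gene or a small RNA, where reads cannot be assigned to a single gene. Rising examples were Copg2 (Mest) in heart, kidney and lung, LTO1 (Ccnd1) and Rpl27a (Snora3) in retina, Sycp3 (Chpt1) in heart, Epo (Gnb2) in heart and kidney and Cnrip1 (Plek) in lung. Falling examples were Ccdc107 (Rmrp) in brain, retina, heart and kidney, Trf (Gm20425) in brain, Ccdc152 (Selenop) in liver and Trim17 (Hist3h2a) in lung.

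By gene, efficiency was called higher for 2753 and lower for 227 of 9952 in brain, 1199 and 191 of 10199 in retina, 598 and 276 of 5583 in heart, 181 and 376 of 8595 in kidney, 246 and 1238 of 6327 in liver and 3490 and 113 of 8855 in lung. Median-of-ratios scaling gave 792 and 994 in brain, 454 and 396 in retina, 69 and 1432 in heart and 503 and 968 in lung. Leaving out mitochondrially encoded genes gave 766 and 246 in retina, 50 and 1490 in heart and 93 and 793 in kidney. Rescaling to an equal sum gave 2784 and 53 in heart, 930 and 191 in kidney, 951 and 577 in liver and 1831 and 322 in lung. Centring on the median gave 946 and 831, 297 and 482, 313 and 446, 263 and 290, 551 and 768, and 617 and 731 in the order above. The filter on low values also turned the direction of most calls in 3 tissues. The stricter filter gave 53 higher and 229 lower of 1911 in heart, and no filter gave 1153 and 641 of 19117 in kidney and 1959 and 1635 of 18897 in liver. With a library left out the totals ranged from 809 to 2016 in retina, 510 to 1027 in heart and 207 to 1392 in kidney, and libraries of the tissue alone gave 38 and 112 in kidney. Genes called under every scaling numbered 787 higher and 218 lower in brain, 292 and 163 in retina, 48 and 53 in heart, 96 and 178 in kidney, 172 and 569 in liver and 496 and 112 in lung.

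**Figure D3:**
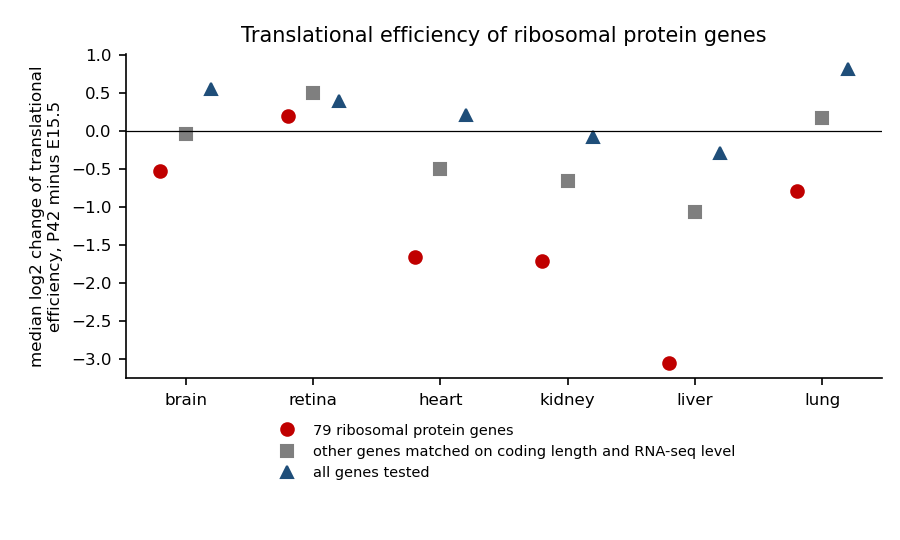
Median log2 change of translational efficiency (P42 minus E15.5) in each tissue for 79 ribosomal protein genes (circles), other genes matched on coding length and RNA-seq level (squares) and all genes tested (triangles); 2 replicates per group. In liver the 3 medians were -3.06, -1.07 and -0.30, and in retina 0.19, 0.49 and 0.39.

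Between tissues at a single stage, 6797 of 7936 genes (85.6%) differed in efficiency at E15.5 and 2924 of 4195 (69.7%) at P42 by a limma F test. The iron storage gene Fth1 lay between -3.58 in retina and -0.08 in liver at E15.5 (adjusted p = 1.87e-07). Ribosomal protein genes, given relative to the median gene of each tissue, lay at -0.44 in brain, -0.65 in retina, -0.57 in heart, -0.72 in kidney, 0.06 in liver and -0.69 in lung at E15.5. At P42 they lay at -1.28, -0.85, -2.25, -2.12, -2.61 and -2.08. The calls were made on ratios without that centring, so they do not test these relative levels. By them 69 of 79 members were called at E15.5, against 85.6% of all genes, and 65 of 79 at P42, against 69.7%. Mitochondrially encoded genes lay at 0.37 in E15.5 liver and between -4.37 and -2.50 in the other E15.5 tissues. They took 0.86% and 0.34% of the TPM total in the E15.5 liver RNA-seq libraries, against 4.72% to 14.98% in the other E15.5 RNA-seq libraries. All E15.5 liver values here rest on those libraries, which also stand apart in histone messages, so library content cannot be separated from translation. The number called fell to 1761 at E15.5 and 1907 at P42 with median-of-ratios scaling, and to 2601 at E15.5 when listed genes were rescaled to an equal sum.

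Replication-dependent histone genes had high footprints and low mRNA values in most E15.5 tissues. Their summed footprints lay between 13178 and 81841 TPM in the E15.5 Ribo-seq libraries and between 545 and 3911 TPM at P42. All 46 tested members fell by footprint in every tissue (adjusted p = 1.6e-06 to 2.11e-24, and adjusted p = 0.292 to 0.631 with an estimated correlation). Their summed mRNA lay between 69.3 and 477 TPM in E15.5 RNA-seq libraries other than liver, and was 29758 and 39214 TPM in the 2 E15.5 liver libraries. Ccdc107, which overlaps the RNA gene Rmrp, was at 1194 and 1615 TPM in those liver libraries and at 22.8 to 88.1 TPM in the other E15.5 RNA-seq libraries.

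**Figure D4:**
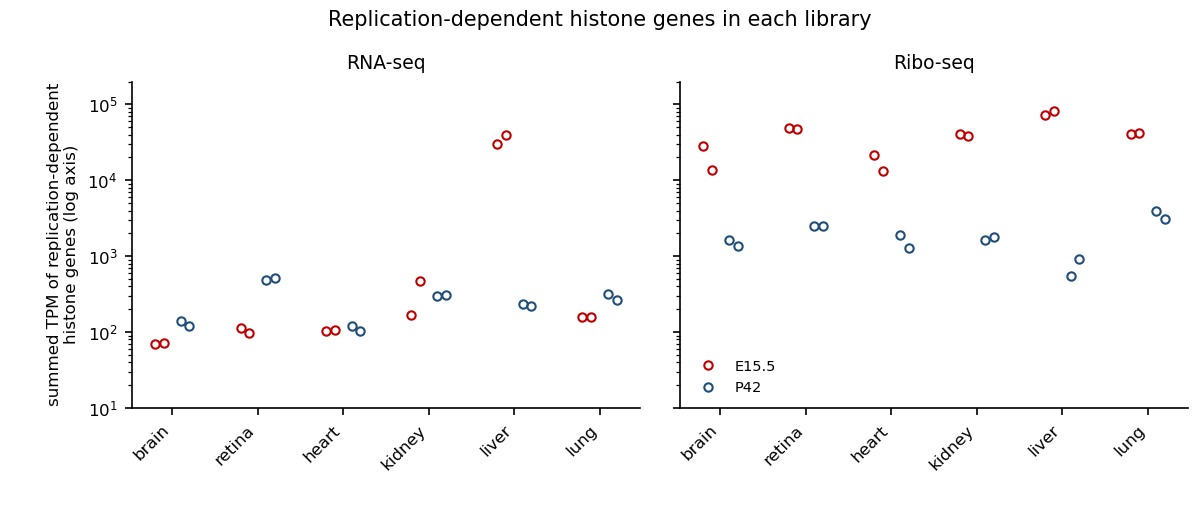
Summed TPM of the replication-dependent histone genes in each library (log axis), by tissue, for RNA-seq and Ribo-seq; red circles are E15.5 and blue circles P42 libraries, 2 per group. The E15.5 liver RNA-seq libraries stand at 29758 and 39214 TPM, against 69.3 to 477 TPM in the other E15.5 RNA-seq libraries.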

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

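Among 131 named genes examined, 34 were called in opposite directions by mRNA in 2 tissues. This set was narrowed after the result was seen. With members of every passing list, whether or not the list fits the tissue, 348 genes were examined and 108 were opposite. The genes were selected on their calls, so a limma test of the difference between tissues restates the selection, and the differences are given as sizes. Differences below are the log2 change (P42 minus E15.5) in the first tissue minus that in the second. For 18 genes the directions stayed opposite under every scaling. The widest was Tnni1, which rose by 2.70 in brain and fell by 10.30 in heart, a difference of 13.003. Others in heart were Myl4 (brain against heart, 10.588), Myh7 (brain against heart, 8.22) and Camk2a (brain against heart, 8.189). Against liver stood Miox (kidney, 12.717), Scgb3a1 (lung, 12.339), Chil3 (lung, 11.488), Chil1 (lung, 11.16), Gfap (brain, 10.451), Mbp (brain, 9.997), Nrgn (brain, 9.89) and Vwf (lung, 4.613). All liver mRNA changes, here and below, rest on the E15.5 liver RNA-seq libraries, which stand apart in histone messages. The scalings tried do not test such a difference in library content. Against kidney stood Alb (brain, 10.134), Cyp11a1 (brain, 7.968), Gfra1 (liver, 7.131), Gdnf (lung, 6.82) and Cldn5 (lung, 4.456), and Ftl1 rose in liver and fell in retina (3.791). The brain rise of Alb rests on P42 RNA-seq replicates far apart, at 2.444 and 22.81 TPM. By footprint the call went the other way in brain for Alb (-1.41) and Myh7 (-1.531) and in liver for Ftl1 (-1.263), and Tnni1 in brain was not called (-0.592). Alb footprints in brain were 1348 TPM at E15.5 against 0.4055 TPM by RNA-seq, and 489.5 against 12.62 TPM at P42. Such footprints of genes that RNA-seq places in another tissue are taken up below, and their source could not be decided.

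For the others the opposite calls were not kept under every scaling. They included Cyp2f2 (liver against heart, 10.525), Hbb-bs (lung against liver, 9.017), Bpifa1 (lung against heart, 8.552), Slc13a3 (kidney against liver, 7.915), H2-Ab1 (lung against retina, 7.459), Aqp4 (retina against heart, 7.444) and Tuba8 (heart against liver, 6.88). They also included Rlbp1 (retina against brain, 6.654), Ckmt2 (heart against liver, 6.613), Ppargc1a (retina against heart, 5.624), Ppara (retina against heart, 5.264), Tmem119 (brain against liver, 4.397), Myh6 (heart against lung, 3.467), Myoz2 (heart against liver, 3.424) and Tnni3 (heart against kidney, 2.584). By footprint the heart call went the other way for Cyp2f2 (2.968). In P42 heart, the ratio to the source tissue was higher by footprint than by RNA-seq for other liver genes (562.6 times) and lung genes (20.09 times). The source of such footprints could not be decided.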

How the results depend on the processing

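Directions of named genes and lists mostly held, while counts depended on scaling and filter. Of 217 named mRNA results, median-of-ratios scaling left 188 the same, 18 weaker, 5 stronger and 6 reversed, and of 273 list results 242 the same and 31 weaker. With an estimated correlation 1 list test passed, against 273. Sequencing depth is unknown, so what it limits could not be measured, and the cause was not tested for any change below unless given.

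Under median-of-ratios scaling, called genes numbered 4415 by mRNA in heart (9878 with the deposited scaling) and 5703 in lung (9090), 3814 by footprint in heart (7609), and for efficiency 1786 in brain (2980), 850 in retina (1390), 1501 in heart (874) and 1471 in lung (3603). Efficiency differences between tissues numbered 1761 at E15.5 (6797) and 1907 at P42 (2924), and genes changed in all tissues 525 by mRNA (1173). Directions reversed for Ppargc1a by footprint in heart (0.053, from -1.205), Hbb-bt in lung (1.045, from -0.27), Hbb-bs in heart (0.209, from -1.81), Ftl1 in heart (0.109, from -1.905) and, for Ftl1, lung (1.203, from -0.113), and Atf4 in heart (0.472, from -1.526) and lung (1.134, from -0.177). After centring on the median, a choice made after seeing the data, counts were 3554 by mRNA in heart and 5732 in lung, 3729 by footprint in heart, 1777, 779 and 1348 for efficiency in brain, retina and lung, and 497 in all tissues by mRNA, and Atf4 in heart reversed to 0.083. Rescaling listed genes to an equal sum, also chosen after seeing the data, gave efficiency counts of 2837 in heart, 1121 in kidney and 2153 in lung and 2601 between tissues at E15.5, and the direction of the histone list in kidney against other genes reversed (median -1.064, adjusted p = 0.961). Leaving out mitochondrially encoded genes gave 1540 for efficiency in heart and 886 in kidney (557).

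A pseudocount of 4 gave footprint counts of 3216, 2699, 4440, 4502, 3996 and 3533 from brain to lung, 2343 enriched genes by footprint at E15.5 (3586), 767 by mRNA and 430 by footprint in all tissues (1173 and 684), and correlations of 0.749 in heart and 0.859 in liver. A pseudocount of 0.25 gave 0.888 in liver. With no filter more genes were tested, and efficiency counts were 4887, 2682, 4976, 1794, 3594 and 6391, and 12286 and 13636 between tissues. Most efficiency calls then turned to higher in kidney (1153 and 641 lower, from 181 and 376) and liver (1959 and 1635, from 246 and 1238). Correlations without it were 0.852 in retina, 0.887 in kidney, 0.848 in liver and 0.825 in lung, and the efficiency of the retinal progenitor list in brain reversed to 0.013 (from -0.625). The stricter filter tested fewer genes and gave 2896 and 4897 by footprint in retina and heart, efficiency counts of 1216, 838, 282, 361, 751 and 1148, 2710 and 571 between tissues, and 440 by footprint in all tissues, and most efficiency calls in heart turned to lower (53 higher and 229 lower, from 598 and 276). Libraries of the tissue alone gave 150 for efficiency in kidney. Spearman correlations were 0.868 in retina, 0.634 in heart, 0.882 in kidney, 0.802 in liver and 0.799 in lung, and with a mean of at least 5 TPM Pearson correlations were 0.761 in heart and 0.906 in liver.

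With a library left out, efficiency counts ranged from 207 to 1392 in kidney, 809 to 2016 in retina and 510 to 1027 in heart, where the lone library is assumed to vary like the other groups. The replication-dependent histone list in kidney ranged from -2.315 without E15.5 kidney RNA-seq replicate 1 to 0.088, reversed, without replicate 2. Libraries share only a replicate number. The replicate block moved no count of calls by over 1.5 times, with 3000 for efficiency in brain (2980) and 620 in kidney (557). Deviations of replicates with a shared number correlated from -0.324 to 0.466 between assays and from -0.488 to 0.297 between stages.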

Other observations

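All 8 adipocyte genes rose in lung by mRNA (adjusted p = 4.2e-09, adjusted p = 0.276 with an estimated correlation). In kidney 26 of 27 erythroid genes fell by mRNA (adjusted p = 2.53e-07, adjusted p = 0.539 with an estimated correlation).

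The explanations below were each tested. Those for carry-over and for E15.5 liver RNA were chosen after the result was seen, and the others were written before. The poly(A) test was written for a lower efficiency of histone genes at P42, and the pattern was renamed, and the deciding value chosen among the 2 written, after its result. Footprints of genes that RNA-seq places in another tissue were found in several Ribo-seq groups. Sftpc footprints were at 370 ± 326 TPM in P42 kidney, where RNA-seq gave 0.282 TPM. Hepatocyte genes rose by footprint in heart for 27 of 29 (adjusted p = 4.73e-20, adjusted p = 0.292 with an estimated correlation). A first form of the tests over all 42 tissue pairs did not decide, with a median correlation of 0.585, and 18 pairs were then chosen on odd-numbered genes and measured on even-numbered genes.

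Reads carried over between Ribo-seq libraries would give footprints in the receiving tissue that follow those in the source, and the median correlation was 0.794, below the bound of 0.8 set for it, so carry-over could not be decided. Tissue of the source organ in the sample could not be decided: in 16 of 18 pairs the footprint ratio was over 5 times the RNA-seq ratio, but the pairs were chosen on that ratio in the same libraries, and the assays are not known to share a dissection. For expression in the receiving tissue, replicates were over 3 times apart in 5 of 18 pairs. This met the bound written against that cause, but the verdict used a stricter bound, under which it could not be decided. Among the 13 others, 9 were over 20 times the RNA-seq ratio and 2 within 5 times, which did not decide it. Footprints of kidney genes in P42 lung were at a median of 3.3% of their level in P42 kidney in replicate 1 and 0.0207% in replicate 2.

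Replication-dependent histone genes had high footprint to RNA-seq ratios at E15.5. Poly(A) selection, which messages without a tail escape, met the bound set for it. The median tailed histone gene lay below the 75th percentile in 6 of 6 tissues, between 21.7 and 62.3. Most sets of genes would lie there too, so this gives little support. The median log2 ratio of the replication-dependent members was 1.149 in E15.5 liver, still at percentile 97.8, and 6.388 to 8.227 in the other E15.5 tissues. The percentile of the members themselves restates the pattern, and a higher ribosome load of their messages was not tested. RNA without poly(A) tails in the E15.5 liver RNA-seq libraries could not be decided, since the gap of 5.239 log2 from the nearest tissue restates the pattern that prompted it.

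Ribosomal protein genes lost translational efficiency against other genes in 5 tissues, though no list passed with an estimated correlation (adjusted p = 0.236 to 0.477) and only 21 of 79 members were called lower in brain and 27 in lung. For a trend with coding length, they lay at least 0.5 log2 below matched genes in 4 of 6 tissues (-0.482 in brain). This met the bound set against the trend as the whole cause. How close the matched genes were in length and level was not checked, so the trend was not excluded. For reads shared with pseudogenes and paralogs, Spearman correlations were -0.081 to 0.212, with none below the bound in 6 of 6 tissues. Members that share more sequence thus did not fall more. The shared part was measured over whole transcripts, and an effect common to all members would give no correlation, so this cause was not excluded. Lower translation of messages with a 5' terminal oligopyrimidine tract fits, as factors with the tract lay at least 0.5 log2 below other factors in 4 of 6 tissues, namely heart, kidney, liver and lung. In brain, where the list also fell against other genes, the difference was 0, so the tract has no support there. In retina the difference was 0.379, and liver rests on E15.5 RNA-seq libraries that stand apart. Factors with and without the tract were not matched on coding length or RNA-seq level, so a trend with these is not separated from the tract. Over other genes, coding length and change correlated (Spearman) at 0.373 to 0.506 in heart, kidney, liver and lung, 0.445 in brain and -0.097 in retina.

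Whether chance can be excluded for the stage difference averaged over tissues was tested with 100 splits of the libraries within each tissue. The real split gave 6717 called genes by mRNA and 4266 by footprint, the highest other split 5695 and 2849, and 1 of 100 splits, the real one, reached the real count in each assay. Other splits mix or swap the stages within tissues, and replicates were much alike, so the real split was likely to rank first. Stage and deposited table coincide, so this rank does not tell a stage difference from a table difference.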
